A study of Homo sapiens with 33 samples.

How the data were processed

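The series holds 33 samples from 2 human cell lines, U2OS (an osteosarcoma line) and IMR90 (fetal lung fibroblasts). Of these, 10 are RNA-seq libraries in 5 groups of 2. They cover U2OS cells given an siRNA against luciferase (the control), NUP153 or NUP93, and IMR90 cells given the control or the NUP153 siRNA. Another 13 are DamID samples, in which a bacterial adenine methyltransferase fused to a protein marks the DNA that the protein approaches. The fusions were to Nup153, Nup93 (mouse), the lamin B receptor (LBR) and GFP, the reference. A further 8 are ChIP-seq or input samples and 2 are DNase-seq samples. Per the labels' protocols, IMR90 cells grew in more serum than U2OS cells and in low oxygen, so culture medium and cell line cannot be separated.

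For RNA, the authors deposited FPKM (fragments per kilobase of transcript, scaled to sequencing depth) for 1 RefSeq transcript per gene symbol. The libraries were strand-specific and selected for polyadenylated RNA, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.1.0, STAR 2.2.0c, HOMER 4.6 and the hg19 build, without saying which tool served which assay; the counting tool and its settings are not given in the sources used here. FPKM are already divided by depth, so no count model was used. The low values still show the depth. Of the low values of short transcripts that were checked, 100% were whole multiples of 1 fragment in each library, within a tolerance of 0.1 step. The step size implied 20.4 to 36.2 M fragments per library (M, 1e6), 16.8 to 25.9 M of them on the listed genes. Replicates of every group differed by more than counting noise (chi-square per degree of freedom 1.58 to 11.0), so no library was treated as a repeat of another. The siNup153 groups differed most, at 10.97 in U2OS and 10.74 in IMR90 cells, against 1.58 to 2.83 in the other groups.

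The other deposited files are lists of genomic intervals on hg19 made by the authors, with no score or fold per interval. Per the file headers, HOMER called the Nup93 list at 2-fold over GFP with at least 100 normalized tags, and the full IMR90 Nup153 list at 2-fold over GFP with at least 50, both in 2500-bp windows. The IMR90 super-enhancers were H3K27ac peaks stitched within 25000 bp and ranked by HOMER, per the file headers. The lists of U2OS Nup153 peaks, IMR90 top Nup153 peaks, U2OS super-enhancers and LBR domains carry no header, so their thresholds are not given in the sources used here, and densities of differently made lists were not read as differences in binding. Each U2OS DamID list is a single list for its replicates, so replicates could not be compared. Both IMR90 Nup153 lists rest on 1 Nup153 sample, with 1 GFP sample in that line. Each ChIP list, the super-enhancers included, also rests on 1 sample. The CTCF header records no control in use. The H3K9me2 list holds 54 intervals with 0.03% of the tags, per the file headers, and was given little weight.

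RNA values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Genes with FPKM of at least 1 in at least 2 of the fitted libraries were tested. The U2OS comparisons shared 1 fit of 6 libraries, the IMR90 comparison used 4, and the difference between the lines' responses was tested as an interaction over all 10. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Gene names and hg19 positions were taken from the deposited table.

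The text names genes by a rule: the targeted genes; per comparison, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose higher mean FPKM is at least 1; up to 4 called members with the largest absolute change from each list that passes camera; the 8 longest super-enhancers with a Nup153 peak per line; and the 12 largest called genes at bound super-enhancers. A few genes taken by the rule are not reported here. There were 23 lists: nucleoporins, nuclear transport factors, nuclear lamina and envelope, osteoblast lineage, fibroblast matrix, DNA replication, mitosis, p53 targets, interferon response, stress of the endoplasmic reticulum (ER) and amino acids, YAP targets, TGF-beta targets, immediate early genes, inflammatory genes, HOX genes, cholesterol synthesis, hypoxia and glycolysis, histone genes, ribosomal proteins, and markers of epithelial, blood, endothelial, and neural and muscle cells. Lists were tested with camera (preset correlation 0.01), which asks whether a list's genes moved more than the other genes. The test was repeated with an estimated correlation, a version that also takes its degrees of freedom from the few libraries of each fit. With so few, a call can be lost without any correlation among the genes. It was also repeated with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. The design, the rule, the lists and the alternatives were fixed before the data were examined, apart from the alternatives named as later additions.

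Interval lists were compared on chromosomes 1 to 22 and X, by an overlap of at least 1 bp, against 10000 circular shifts of the peaks along each chromosome, which keep their spacing and width. The chromosome span was taken as the largest interval end in any list, since no hg19 genome was used here. The smallest p these shifts can give is 0.0001. Tests were one-sided toward the side observed, with Benjamini-Hochberg adjustment over all pairs. Each super-enhancer was given the nearest start site among tested genes. Medians were compared by a two-sided permutation test with 100000 resamples and shares by Fisher's exact test. Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1 were used.

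The methods were tested on simulated data. With 12784 simulated genes, the U2OS siNup153 comparison recovered 18% of genes changed by 0.25 (log2), 82% by 0.5, 98% by 1 and 100% by 2, and the siNup93 comparison 4%, 80%, 90% and 98%. The IMR90 comparison (11916 genes) recovered 22%, 96%, 96% and 100%, and the interaction (13729 genes) 4%, 68%, 92% and 96%. Between 11 and 22 unchanged genes were called. Beside at most 50 recovered genes per size of change, these were more than a share of 0.05 of the calls in each comparison. The threshold was thus exceeded in these simulations, where few genes changed. Of 100 sets of random peaks, 2 passed 0.05 against the U2OS super-enhancers. With 10 peaks placed there among 1000, the permutation by circular shifts gave p = 0.0075. The alternatives were other pseudocounts, filters, scalings, fits and overlap rules, the replicate number as a block, and each library left out in turn.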

Results

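The transcriptomes of U2OS and IMR90 cells were measured after knockdown of Nup153, a nucleoporin of the nuclear basket of the nuclear pore complex. In U2OS cells Nup93, a scaffold nucleoporin of the pore, was also knocked down. Each of the 5 groups had 2 RNA libraries, and each library held 20.4 to 36.2 M fragments (M, 1e6) as implied by its FPKM steps. Between 11382 and 12198 genes reached an FPKM of 1 per library. DamID gave 1851 Nup153 and 1021 Nup93 peaks in U2OS cells, and 24595 Nup153 peaks in IMR90 cells with a top list of 1851. They were compared with super-enhancers (long clusters of H3K27ac-marked enhancers, 345 in U2OS and 596 in IMR90 cells), with LBR domains, which mark chromatin at the nuclear lamina, and with other chromatin features. The title of the series places the work around nucleoporins and cell identity genes. FPKM are given below as mean ± SD with n = 2 libraries per group.

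NUP153 (chromosome 6, 17615266 to 17707065, hg19) fell in U2OS cells given its siRNA from 31.7 ± 1.06 to 12.8 ± 0.91 FPKM, 40.4% of the control. In IMR90 cells it fell from 20.8 ± 0.245 to 3.42 ± 0.283 FPKM, 16.4% of the control. The log2 fall was greater in IMR90 cells by an interaction of -1.06 (limma adjusted p = 1.23e-05). NUP93 (chromosome 16, 56764017 to 56878861) fell with its own siRNA from 37.0 ± 1.36 to 2.88 ± 0.23 FPKM, 7.78% of the control. Each transcript was higher in U2OS cells when the other was depleted. NUP93 reached 50.4 ± 1.49 FPKM with siNup153 (log2 fold change 0.44, adjusted p = 0.00124), and NUP153 reached 40.5 ± 0.312 FPKM with siNup93 (0.34, adjusted p = 0.00247). In IMR90 cells NUP93 was 26.9 ± 0.169 FPKM with siNup153 against 32.3 ± 0.856 (-0.26, adjusted p = 0.00688), a call lost without control replicate 1 (adjusted p = 0.083) or control replicate 2 (0.167).

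**Figure D1:**
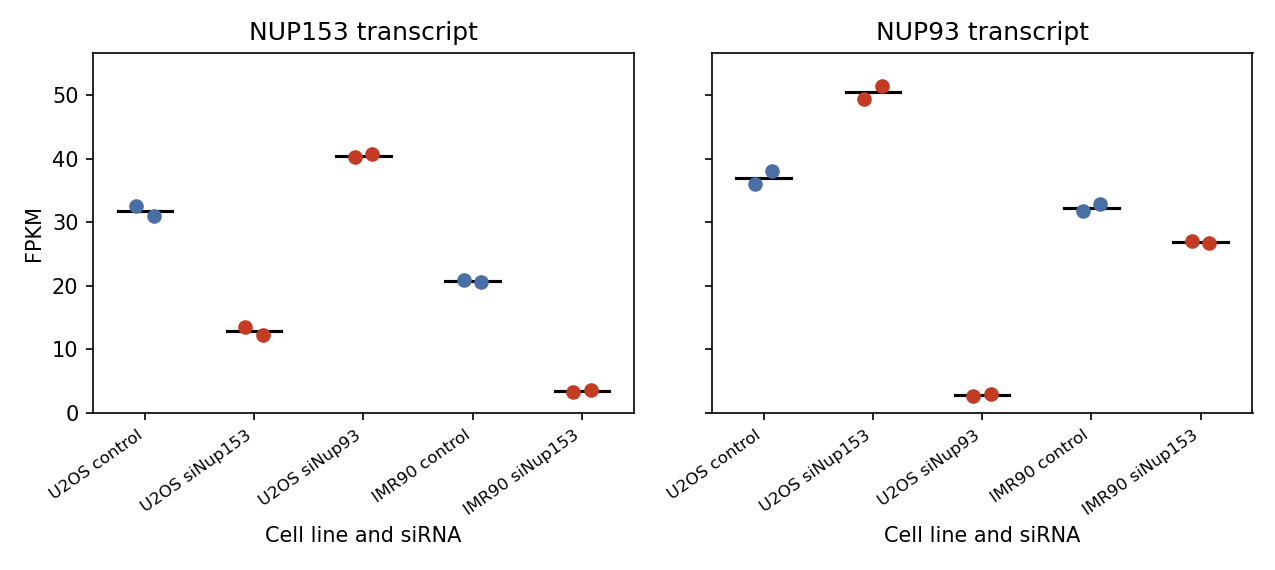
FPKM of NUP153 (left) and NUP93 (right) in each of the 10 RNA libraries, by cell line and siRNA; points are libraries (blue for control, red for knockdown) and bars are the means of 2. NUP153 was at 12.8 FPKM in U2OS and 3.42 FPKM in IMR90 cells with siNup153, and NUP93 at 2.88 FPKM with siNup93.

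Knockdown of Nup153 in U2OS cells raised 3934 and lowered 3750 of 12784 genes tested, 390 and 256 of them by at least 2-fold (688 and 567 with a pseudocount of 0.1). Among the largest rises, the interleukin-7 receptor gene IL7R (chromosome 5, 35856977 to 35879705) went from 10.8 ± 0.164 to 90.8 ± 7.56 FPKM, and SNAPC1 (chromosome 14, 62229075 to 62263146), a subunit of the snRNA-activating complex, from 22.7 ± 0.868 to 186.1 ± 11.8. TMEM45A rose from 2.08 ± 0.554 to 23.4 ± 1.41 FPKM, GPRC5A from 11.4 ± 0.95 to 69.6 ± 1.01, and SDPR and the growth factor gene PTN by 2.53 and 2.60 on the log2 scale. LINC01468 went from 0.05 to 9.09 FPKM. COX7C and COX7A2, subunits of cytochrome c oxidase, rose by 3.03 and 2.99, but they and LOC100505715 (2.61) are uncertain, since near-identical copies or overlapping transcripts can share their reads. The largest fall was that of FAP (chromosome 2, 163027194 to 163100045), a cell-surface protease of activated fibroblasts, from 14.8 ± 0.0276 to 1.45 ± 0.0148 FPKM. SEMA7A fell from 98.4 ± 1.84 to 15.7 ± 1.61, the chromatin gene HMGA2 from 125.9 ± 4.09 to 22.9 ± 0.878, the actin-binding gene TAGLN from 389.1 ± 13.6 to 84.3 ± 6.55, and IGFBP7 from 70.6 ± 4.62 to 15.8 ± 0.4. MGP (-2.46), LCP1 (-2.05), TPRG1L (-2.19), C8orf4 (-2.29) and LOC102467080 (-2.44) fell as well. Adjusted p for these 20 genes lay between 7.29e-06 and 5.71e-05.

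Genes of the cell division cycle rose together in U2OS cells given siNup153. All 24 DNA replication genes rose, and 24 when adjusted over the list alone, with a median log2 fold change of 1.06. CDC45, a component of the replicative helicase, went from 16.4 ± 1.08 to 46.0 ± 1.72 FPKM, MCM4 from 24.6 ± 0.175 to 65.2 ± 0.0163, and MCM2 and GINS1 rose by 1.87 and 1.37. Camera gave adjusted p = 7.69e-11, and adjusted p = 0.206 with an estimated correlation. Of 24 mitosis genes 22 rose (23 adjusted over the list alone), among them CDC20, PLK1, BIRC5 and AURKA by 1.43, 1.31, 1.11 and 1.1025 (camera adjusted p = 1.03e-08; adjusted p = 0.206 with an estimated correlation). Of 31 nucleoporin genes 21 rose and 4, the targeted NUP153 among them, fell (21 and 4 adjusted over the list alone), the rises led by NDC1 (1.24), SEC13 (0.91) and NUP58 (0.83; camera adjusted p = 0.00229; adjusted p = 0.422 with an estimated correlation). Without NUP153 the list gave 21 rises and 3 falls of 30 (camera adjusted p = 0.000544; adjusted p = 0.403 with an estimated correlation). Of 31 nuclear transport factors 17 rose and 4 fell (18 and 4 adjusted over the list alone), and KPNB1, which encodes importin beta, went from 96.0 ± 1.4 to 209.3 ± 12.7 FPKM. RCC1, RANBP1 and CSE1L rose by 0.81, 0.73 and 0.65 (camera adjusted p = 0.00809; adjusted p = 0.492 with an estimated correlation).

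Interferon response genes, fibroblast matrix genes and TGF-beta targets went the other way. Of 10 interferon response genes 9 fell (9 adjusted over the list alone), including IRF9, the RNA sensors DDX58 and IFIH1, and OAS3 (-1.12, -0.96, -0.87 and -0.72) (camera adjusted p = 0.00373; adjusted p = 0.269 with an estimated correlation). Of 18 fibroblast matrix genes 11 fell and 4 rose (12 and 4 adjusted over the list alone). After quantile scaling 11 fell and 0 rose, so the rises depended on the scaling. Fibronectin (FN1) went from 308.4 ± 0.115 to 106.8 ± 1.39 FPKM, and the collagen genes COL5A1 and COL3A1 fell by 1.73 and 1.72 (camera adjusted p = 0.00905; adjusted p = 0.328 with an estimated correlation). Of 16 TGF-beta targets 11 fell and 3 rose (11 and 3 adjusted over the list alone), with BHLHE40 and SMAD7 falling by 0.96 and 0.70 while ID3 rose by 1.00 (camera adjusted p = 0.0449; adjusted p = 0.517 with an estimated correlation). YAP targets rose in 9 of 14 and fell in 3 (9 and 3 adjusted over the list alone), ANKRD1, AXL, F3 and AMOTL2 by 1.15, 1.13, 0.91 and 0.83 (camera adjusted p = 0.0449; adjusted p = 0.328 with an estimated correlation). In the hypoxia and glycolysis list 11 of 17 rose and 3 fell (11 and 3 adjusted over the list alone), with LDHA, BNIP3 and ADM rising by 1.075, 0.96 and 0.77, while P4HA1 fell by 0.60 (camera adjusted p = 0.0449; adjusted p = 0.328 with an estimated correlation).

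Of 30 ribosomal protein genes 15 rose and 1 fell (11 and 1 adjusted over the list alone; 5 and 4 after quantile scaling, where the median was 0.097 against 0.216), RPS2 and RPL11 by 0.69 and 0.53, though many pseudogenes can share their reads (camera adjusted p = 0.0336; adjusted p = 0.517 with an estimated correlation). RPS15 stood at 0.50, a call lost without control replicate 1 (adjusted p = 0.131) or control replicate 2 (0.103). The epithelial markers tested were mostly keratins, which U2OS cells also express, and 5 of 5 rose (5 adjusted over the list alone), KRT8 by 0.86 and KRT18 by 0.53 (camera adjusted p = 0.0449; adjusted p = 0.422 with an estimated correlation). CLDN4 (0.74) lost its call without control replicate 1 (adjusted p = 0.0702), and KRT7 (0.59) lost it without that library (0.147), without siNup153 replicate 2 (0.0673) or without siNup93 replicate 1 or 2 (0.0551 and 0.0554). Camera did not call the lamina and envelope list (median 0.40, adjusted p = 0.198), histone genes (0.46, 0.0805), p53 targets (0.17, 0.275), ER and amino-acid stress (0.17, 0.362), immediate early genes (0.15, 0.388), inflammatory genes (-0.12, 0.116), HOX genes (0.09, 0.676), cholesterol synthesis (0.09, 0.362), osteoblast lineage (-0.15, 0.511) or neural and muscle markers (-0.26, 0.116).

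Knockdown of Nup93 in U2OS cells raised 4628 and lowered 4063 of the same 12784 genes, 836 and 611 by at least 2-fold (1185 and 1003 with a pseudocount of 0.1). Among the largest rises, CSF2 (chromosome 5, 131409485 to 131411863), the cytokine GM-CSF, went from 0.434 ± 0.0205 to 33.8 ± 6.11 FPKM, CXCL8 (interleukin-8) from 6.66 ± 0.421 to 74.6 ± 12.5, and SAA1 (serum amyloid A) from 2.65 ± 0.0297 to 43.2 ± 1.17. SPP1 (osteopontin) rose from 12.2 ± 0.46 to 107.2 ± 0.136 FPKM, the autophagy receptor gene SQSTM1 from 21.8 ± 1.13 to 216.8 ± 14.6, and TMEM45A, SRGN, ADAMTS1, LY96 and SDPR by 3.93, 3.42, 3.24, 3.22 and 3.10. Besides NUP93, the largest falls were those of HIST1H2BK, from 230.6 ± 13.8 to 12.8 ± 1.58 FPKM, and ADGRG1 (chromosome 16, 57653605 to 57698951), an adhesion receptor, from 37.5 ± 0.00919 to 1.802 ± 0.0134. FAP (-3.39), LOC79160 (-3.13), TAGLN (-3.05), LTBP3 (-2.99), KLHDC8A (-2.90), CNN2 (-2.81) and IGFBP7 (-2.81) fell as well. Reads of HIST1H2BK and of SAA1 can be shared with close paralogs, so both values are uncertain. Adjusted p for these genes lay between 1.97e-06 and 5.14e-05.

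Of 15 inflammatory genes 13 rose with siNup93 and none fell (13 adjusted over the list alone), with a median log2 fold change of 1.64. MMP1 went from 0.0765 ± 0.0587 to 7.28 ± 0.861 FPKM and IL1A from 1.11 ± 0.194 to 13.4 ± 1.16 (camera adjusted p = 5.8e-05; adjusted p = 0.368 with an estimated correlation), and CXCL3 rose by 2.86. In the ER and amino-acid stress list 17 of 20 rose and 1 fell (17 and 1 adjusted over the list alone), among them ATF3, the serine synthesis gene PSAT1, ASNS (asparagine synthetase) and DDIT3 by 2.30, 1.64, 1.46 and 1.31 (camera adjusted p = 0.000115; adjusted p = 0.255 with an estimated correlation). DNA replication genes rose in 21 of 24 and fell in 1 (21 and 1 adjusted over the list alone), RRM2, MCM2, CDC45 and GINS1 rising by 1.57, 1.5046, 1.14 and 1.14 (camera adjusted p = 1.06e-05; adjusted p = 0.255 with an estimated correlation). Mitosis genes rose in 18 of 24 and fell in 3 (18 and 3 adjusted over the list alone). CDC20, AURKA and PLK1 rose by 0.99, 0.98 and 0.92 and CENPF fell by 0.83 (camera adjusted p = 0.0116; adjusted p = 0.368 with an estimated correlation). Of 21 p53 targets 13 rose and 3 fell (14 and 3 adjusted over the list alone), GADD45A, DDB2 and MDM2 rising by 2.17, 1.30 and 1.18 and TP53I3 falling by 1.33 (camera adjusted p = 0.0365; adjusted p = 0.369 with an estimated correlation).

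TGF-beta targets fell in 12 of 16 and rose in 2 with siNup93 (13 and 2 adjusted over the list alone), with a median of -0.80. PMEPA1 went from 81.0 ± 1.79 to 13.4 ± 0.461 FPKM, TGFBI from 60.05 ± 2.56 to 10.6 ± 0.373, and SKI fell by 1.37 (camera adjusted p = 0.000327; adjusted p = 0.368 with an estimated correlation). Fibroblast matrix genes fell in 12 of 18 and rose in 2 (12 and 2 adjusted over the list alone), COL6A3 from 43.5 ± 1.13 to 5.79 ± 0.543 FPKM and FN1 from 308.4 ± 0.115 to 88.3 ± 0.803 (camera adjusted p = 0.0021; adjusted p = 0.319 with an estimated correlation). COL5A1 fell by 1.87. Of 19 cholesterol synthesis genes 13 fell and 2 rose (14 and 2 adjusted over the list alone), LSS (-0.93), MSMO1 (-0.88) and DHCR7 (-0.87) among the falls, while ACAT2 rose by 1.01 (camera adjusted p = 0.00426; adjusted p = 0.283 with an estimated correlation). Polyadenylated histone transcripts fell in 9 of 12 and rose in 1 (9 and 1 adjusted over the list alone), HIST1H4H (-2.15), HIST1H2BD (-1.81) and HIST2H2BE (-1.59) among the falls (camera adjusted p = 0.00226; adjusted p = 0.437 with an estimated correlation). Camera did not call nucleoporins (median 0.20, adjusted p = 0.144; 0.27 and 0.0862 without the targeted NUP93), transport factors (0.06, 0.264; median -0.02 after quantile scaling), lamina and envelope (0.26, 0.334, with a median of 0.13 after quantile scaling), YAP targets (0.25, 0.144), hypoxia and glycolysis (0.38, 0.101), immediate early genes (0.37, 0.144), interferon response (-0.23, 0.264), HOX genes (-0.19, 0.0948), osteoblast lineage (0.26, 0.264), ribosomal proteins (-0.04, 0.144; median -0.13 after quantile scaling), or epithelial (0.47, 0.144) and neural and muscle markers (0.08, 0.522).

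The responses to the 2 knockdowns in U2OS cells ran in the same direction for many genes. Of the 12784 genes, 2729 rose and 2273 fell in both, where independent lists would share 1424 and 1192, and 942 were called in opposite directions against 2608. At least 2-fold changes in both numbered 224 rises and 118 falls (422 and 234 with a pseudocount of 0.1). Across genes, which are not independent replicates, Pearson's r was 0.588 and the covariance 0.196. Both comparisons used the same control libraries. In 50 simulations, all 6 libraries, controls included, were drawn around 1 mean per gene with the spread of the fit. Sharing the simulated controls gave a mean r of 0.497 and a mean covariance of 0.00504, with at most 1 gene rising and 1 falling in both. With 1 control library given to each knockdown, so that none was shared, r was 0.572 or 0.604 by which control went to which, 1682 or 1646 genes rose in both (805 or 773 expected), 1164 or 1162 fell (558 or 515 expected), and 219 or 227 rose and 86 fell at least 2-fold in both.

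In IMR90 cells, knockdown of Nup153 raised 4910 and lowered 2742 of 11916 genes, 608 and 386 by at least 2-fold (1091 and 548 with a pseudocount of 0.1). Which side of the 2-fold changes was larger depended on the scaling, with 426 rises and 537 falls in centred libraries and 422 and 516 after quantile scaling. The median of all genes stood at 0.12 on the log2 scale. With libraries centred on their medians the split was 3675 rises to 3689 falls, and after quantile scaling 3765 to 3429, against 64.2% rises as deposited. The largest rises were those of BMF (chromosome 15, 40380092 to 40398287), a pro-apoptotic member of the BCL2 family, from 1.42 ± 0.0863 to 56.7 ± 1.07 FPKM, and RASGRP3 (chromosome 2, 33738942 to 33789798), from 0.91 ± 0.194 to 39.0 ± 3.98. The transcription factor gene SOX4 rose from 6.28 ± 0.087 to 55.8 ± 2.79 FPKM, and HTRA3 from 5.32 ± 0.16 to 61.7 ± 7.62. SLITRK6, VWA5A, COLEC10, SCG2, MFAP2 and FAM105A rose by 3.62, 3.22, 3.18, 3.17, 3.13 and 2.91. IGFBP3 (chromosome 7, 45951844 to 45960871), a secreted binding protein of insulin-like growth factors, fell from 566.1 ± 5.87 to 13.9 ± 0.279 FPKM, the largest fall. CD274, which encodes the immune checkpoint ligand PD-L1, fell from 33.2 ± 0.367 to 4.99 ± 0.146. CEMIP (-3.13), SERPINB2 (-2.88), KRT7 (-2.63), CLDN11 (-2.62), OXTR (-2.58), KISS1 (-2.55) and SSTR1 (-2.52) fell as well. Adjusted p for these genes was at most 1.26e-08 except for KISS1 (0.00267).

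Division genes fell together in IMR90 cells given siNup153. All 24 mitosis genes fell, and 24 adjusted over the list alone, with a median of -0.83. CDC20 went from 129.0 ± 0.493 to 39.9 ± 3.61 FPKM, and PLK1 (-1.35), CDCA8 (-1.32) and AURKA (-1.26) fell (camera adjusted p = 7.57e-15; adjusted p = 0.19 with an estimated correlation). Of 24 DNA replication genes 23 fell (23 adjusted over the list alone), RRM2 (-1.27), UHRF1 (-1.07), TYMS (-1.03) and MCM10 (-0.89) among them (camera adjusted p = 1.14e-09; adjusted p = 0.19 with an estimated correlation). Of 22 p53 targets 18 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 1.199. GDF15 went from 1.90 ± 0.217 to 9.71 ± 1.47 FPKM and ZMAT3 from 3.82 ± 0.117 to 15.3 ± 1.8 (camera adjusted p = 5.88e-05; adjusted p = 0.196 with an estimated correlation), and BBC3 and RRM2B rose by 1.54 and 1.5027.

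Of 15 YAP targets 13 fell (13 adjusted over the list alone). The matricellular genes CTGF and CYR61 went from 748.6 ± 2.33 to 191.0 ± 1.02 and from 383.5 ± 8.33 to 113.2 ± 1.43 FPKM, and CRIM1 (-1.47) and ANKRD1 (-1.45) fell (camera adjusted p = 1.32e-07; adjusted p = 0.196 with an estimated correlation). Inflammatory genes fell in 11 of 15 (11 adjusted over the list alone), MMP1 from 617.4 ± 6.56 to 214.0 ± 12.8 FPKM, and MMP10 (-2.41), PTGS2 (-2.12) and IL6 (-1.39) among them (camera adjusted p = 1.13e-06; adjusted p = 0.196 with an estimated correlation). Transport factors fell in 17 of 31 and rose in 5 (17 and 5 adjusted over the list alone), with IPO4 (-1.51), KPNA3 (-1.19) and KPNA2 (-1.078) among the falls and KPNA5 (1.22) among the rises (camera adjusted p = 5.29e-05; adjusted p = 0.216 with an estimated correlation). Nucleoporins fell in 18 of 30, the targeted NUP153 (-2.30) included, and rose in 3 (19 and 3 adjusted over the list alone), NUP50 (-0.89), SEH1L (-0.88) and NUP35 (-0.72) among the other falls (camera adjusted p = 6.95e-05; adjusted p = 0.216 with an estimated correlation). Without NUP153 the list gave 17 falls and 3 rises of 29 (camera adjusted p = 0.000219; adjusted p = 0.216 with an estimated correlation). Lamina and envelope genes fell in 9 of 17 and rose in 1 (9 and 1 adjusted over the list alone), LMNB2 (-0.98), SUN1 (-0.66), SUN2 (-0.61) and LMNB1 (-0.61) among the falls (camera adjusted p = 0.00151; adjusted p = 0.196 with an estimated correlation). In the hypoxia and glycolysis list 12 of 17 fell and 3 rose (12 and 3 adjusted over the list alone), SLC2A1 (-1.41), ADM (-1.39), PDK1 (-0.97) and HK2 (-0.86) among the falls (camera adjusted p = 0.000497; adjusted p = 0.196 with an estimated correlation).

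Cholesterol synthesis genes rose in 14 of 19 and fell in 1 in IMR90 cells (14 and 1 adjusted over the list alone). MSMO1 went from 8.28 ± 0.363 to 27.8 ± 3.33 FPKM, and STARD4, SREBF2 and INSIG1 rose by 1.37, 1.33 and 1.26 (camera adjusted p = 0.001; adjusted p = 0.196 with an estimated correlation). HOX genes rose in 7 of 12 (7 adjusted over the list alone), HOXA5 from 6.11 ± 0.024 to 25.2 ± 1.23 FPKM and HOXA4, HOXA3 and HOXA7 by 1.28, 1.23 and 1.06 (camera adjusted p = 0.0475; adjusted p = 0.251 with an estimated correlation). Immediate early genes fell in 11 of 18 and rose in 5 (11 and 5 adjusted over the list alone), MYC (-1.70), FOSL1 (-1.46) and DUSP1 (-1.32) among the falls and EGR2 (1.09) among the rises (camera adjusted p = 0.00608; adjusted p = 0.323 with an estimated correlation). Of 5 epithelial markers, keratins among them, 4 fell (4 adjusted over the list alone), KRT19 (-1.02) and KRT18 (-0.43) among them (camera adjusted p = 0.00307; adjusted p = 0.196 with an estimated correlation). CLDN4 stood at -0.52, a call lost without control replicate 1 (adjusted p = 0.0928) or siNup153 replicate 1 (0.0965). Camera did not call interferon response (median 0.35, adjusted p = 0.0605), osteoblast lineage (0.36, 0.111), ER and amino-acid stress (0.29, 0.137), fibroblast matrix (-0.03, 0.154), histone genes (0.75, 0.183), TGF-beta targets (0.14, 0.479, with the test on the side of falls) or ribosomal proteins (0.04, 0.568, with the test on the side of falls). With centred libraries these 7 medians were 0.23, 0.23, 0.17, -0.15, 0.62, 0.01 and -0.08, in the order given. For ribosomal proteins 7 passed as rises and 5 as falls as deposited, 1 and 10 with centred libraries, and 19 and 2 after quantile scaling (median 0.22), so no direction is given. Every list called in IMR90 cells kept the sign of its median with centred and with quantile-scaled libraries. Fry called every list that camera called in the 3 knockdowns. Blood markers had too few expressed genes for any test, and endothelial markers could be tested only across all 10 libraries, where 2 were expressed (interaction median -0.06, or -0.16 with centred libraries; adjusted p = 0.851).

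**Figure D2:**
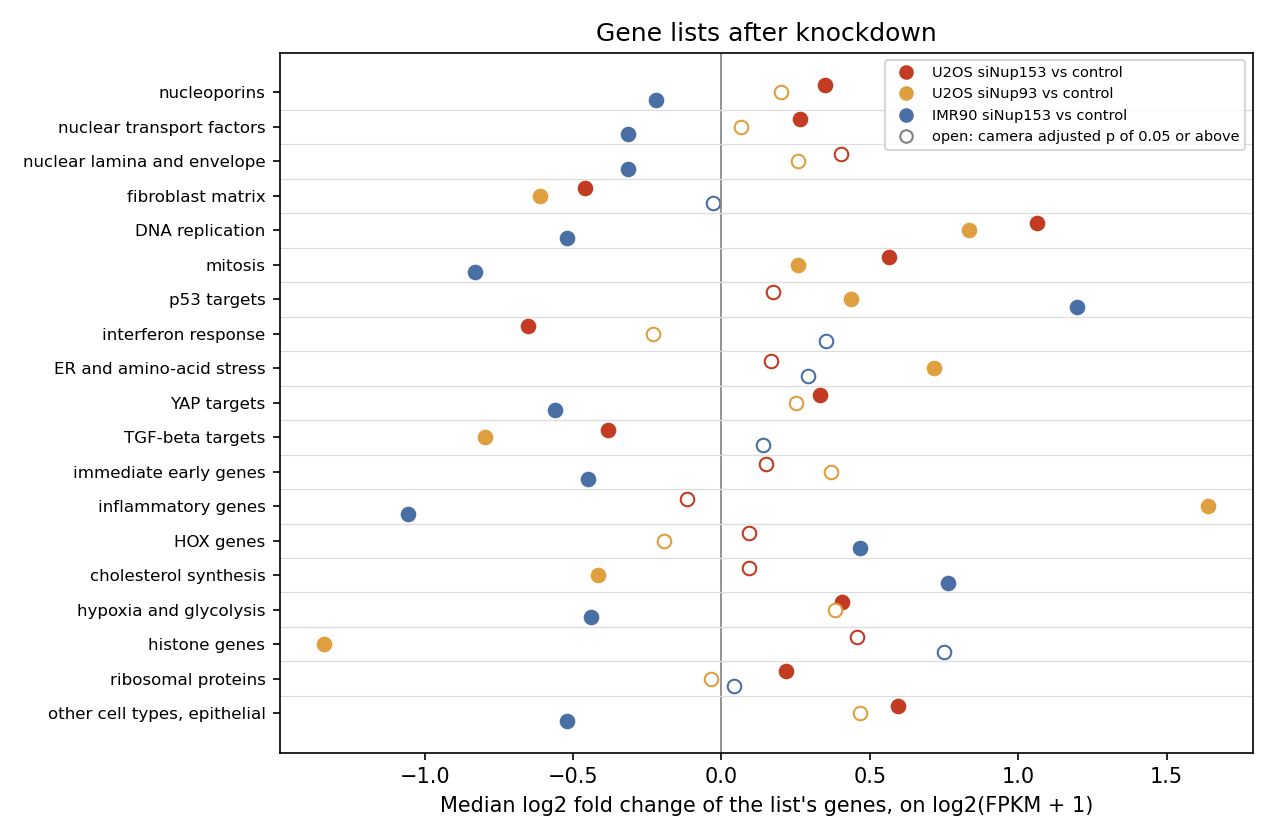
Median log2 fold change, on log2(FPKM + 1), of the genes of each list that camera called in at least 1 knockdown (vertical axis) for the 3 knockdowns against their controls; filled points passed camera at 0.05. DNA replication stood at 1.06 with siNup153 and 0.84 with siNup93 in U2OS cells and at -0.52 with siNup153 in IMR90 cells.

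The response to siNup153 differed between the cell lines. In the interaction test, 5350 of 13729 genes responded more positively in IMR90 and 3825 more negatively. The median difference of all genes stood at 0.11, so the balance of these 2 counts can move with the scaling of the libraries. Division genes rose in one line and fell in the other. The DNA replication list differed by a median of -1.62 and the mitosis list by -1.36, with 24 of 24 genes past the threshold in each (24 adjusted over the list alone), and both held with an estimated correlation (adjusted p = 0.0258). YAP targets differed by -1.19 in 14 of 15 genes (14, and 1 the other way, adjusted over the list alone; adjusted p = 0.0498 with an estimated correlation). The receptor tyrosine kinase gene MET rose by 1.84 in U2OS and fell by 1.82 in IMR90 cells, and CDC20 rose by 1.43 and fell by 1.67, whereas PIK3IP1 and NREP fell by 1.70 and 1.48 in U2OS and rose by 1.76 and 2.05 in IMR90 cells. MET, PIK3IP1 and NREP were named after their values were seen. Of 10991 genes tested in both lines, 1045 rose and 565 fell in both, where independent lists would share 1389 and 743, and 2912 were called in opposite directions against 2092. Across genes, which are not independent replicates, Pearson's r was -0.21 and Spearman's rho -0.24.

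**Figure D3:**
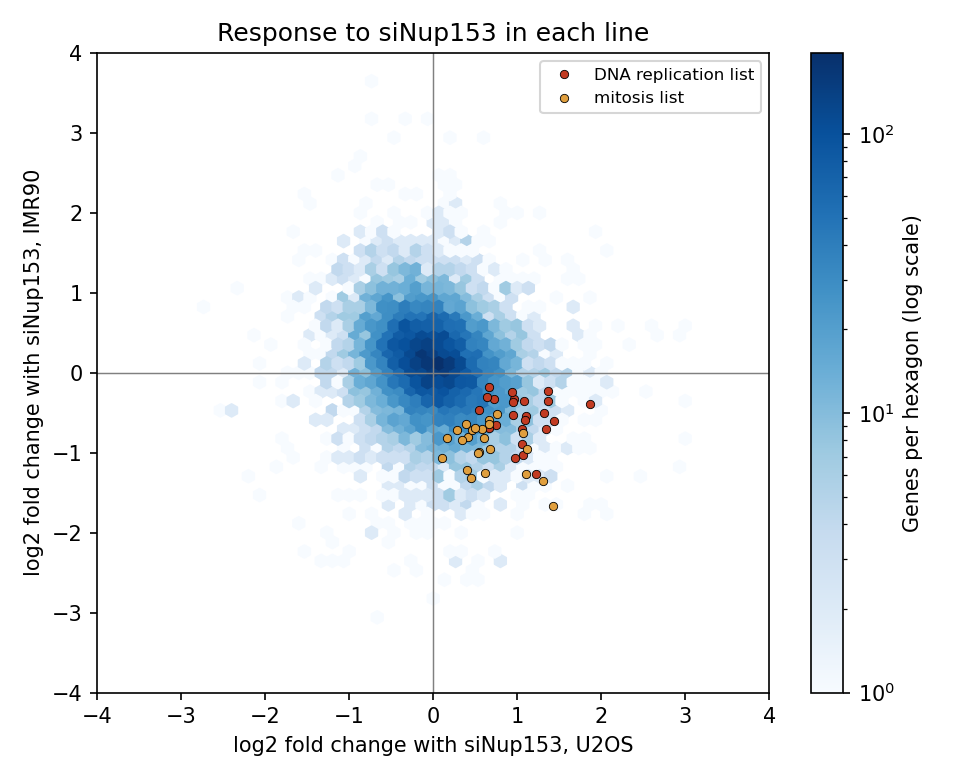
Log2 fold change with siNup153 in U2OS (horizontal) and IMR90 cells (vertical), on log2(FPKM + 1), with hexagons shaded by number of genes on a log scale and the genes of the DNA replication (red) and mitosis (orange) lists as points. The 10991 genes tested in both lines gave r = -0.21, and the 24 DNA replication and 24 mitosis genes lay to the right of 0 and below 0.

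Nup153 and Nup93 DamID peaks of U2OS cells lay in super-enhancers far more often than shifted peaks. Of 1822 Nup153 peaks on the chromosomes used, 264 (14.5%) overlapped a super-enhancer against 14.98 expected, a ratio of 17.6, and of 993 Nup93 peaks 167 (16.8%) did against 9.36, a ratio of 17.8. Against peaks placed on random DNase sites the ratios were 4.39 and 5.11. Seen from the super-enhancers, 173 of 344 (50.3%) held a Nup153 peak and 103 (29.9%) a Nup93 peak. Both proteins marked 86 of them, Nup153 alone 87, Nup93 alone 17 and neither 154 (odds ratio 8.96, Fisher's exact p = 1.66e-16). Marked super-enhancers were longer (median 55.65 kb against 43.85 kb for Nup153, 61.65 kb against 45.37 kb for Nup93), which by itself favours joint marking. In IMR90 cells 333 of 1847 top Nup153 peaks (18.03%) lay in super-enhancers against 69.6 expected, a ratio of 4.79, and 171 of 596 super-enhancers (28.7%) held one. The full IMR90 list gave 2466 of 24554 peaks against 852.6, a ratio of 2.89, which is 1.5 times or more below that of the top list. In U2OS super-enhancers the IMR90 lists gave ratios of 5.57 (top) and 2.94 (full), no lower than in those of their own line. U2OS Nup153 peaks gave 4.77 in IMR90 super-enhancers. Adjusted p was 0.0001 in each, the smallest the shifts can give. Among the longest U2OS super-enhancers with a Nup153 peak were those nearest SMAD3 (chromosome 15, 67290035 to 67472592, 2 peaks), ZFP36L1 (chromosome 14, 68909630 to 69066614, 1 peak), MYH9 (chromosome 22, 36723647 to 36877562, 3 peaks), COPS8 (3), APOLD1 (4), UACA (2), SERTAD2 (2) and CALM2 (2). In IMR90 cells they were those nearest UBE2V1 (chromosome 20, 48702316 to 49192432, 3 peaks), SOCS5 (3), TES (1), COPS8 (1), TPM1 (1), AHNAK (2), CTIF (1) and RHEB (1).

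The peaks of the 2 nucleoporins overlapped each other and other marks of active chromatin. Of 993 Nup93 peaks 364 (36.7%) overlapped a Nup153 peak against 4.57 expected (348 against 2.26 with 0.5 of the peak inside). U2OS cells have 2 GFP samples besides the 1 for LBR, so the lists may share their reference. Its part in the overlap was not tested, and the shifts do not hold open chromatin fixed. DNase sites, which mark open chromatin, lay in 60.4% of Nup153 and 52.2% of Nup93 peaks by replicate 1, 6.14 and 4.87 times the expectation, and in 55.5% and 49.0% by replicate 2. H3K4me3, a promoter mark, was found at 14.6% and 17.3% (6.73 and 6.86 times; 12.8 and 8.41 times when 0.5 of a peak had to lie inside), and CTCF, a protein that anchors chromatin loops, at 10.6% and 12.7% (3.58 and 4.02 times). Adjusted p was 0.0001 in each. H3K9me2 intervals, of which 50 remained, met 2 Nup153 peaks (0.106 expected, adjusted p = 0.0064) and 0 Nup93 peaks (0.0579 expected, adjusted p = 0.944). In IMR90 cells 899 of 1847 top Nup153 peaks (48.7%) met H3K4me3, 5.28 times the expectation (116 and 47.7 times with 0.5 of the peak inside), but these peaks were wider, with a median of 10.6 kb against 2.501 kb for U2OS peaks. In a central window of 2.5 kb the shares were 25.4% in IMR90 and 14.2% in U2OS cells (Fisher's exact p = 7.22e-18), from lists made with different or unstated thresholds. The test counts peaks and does not measure the spread between samples, with 1 Nup153 sample in IMR90 cells and 1 H3K4me3 sample per line.

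**Figure D4:**
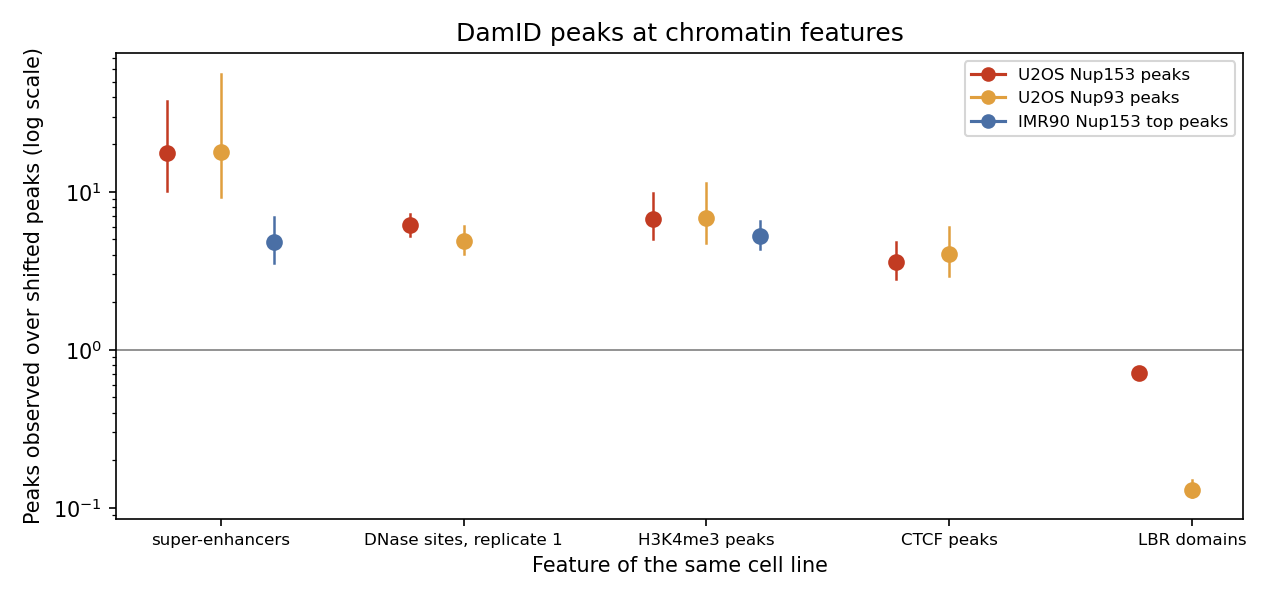
Number of DamID peaks at each chromatin feature of the same cell line over the mean of 10000 circular shifts, on a log axis; lines give the same ratio over the ends of the range that held 95% of the shifted numbers. Ratios at super-enhancers were 17.6 (U2OS Nup153), 17.8 (U2OS Nup93) and 4.79 (IMR90 Nup153), and at LBR domains 0.714 and 0.13.

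Both nucleoporins were found less often than shifted peaks in LBR domains. LBR domains covered 56.0% of the span. Of the Nup153 peaks 691 (37.9%) touched one against 53.1% expected, and of the Nup93 peaks 61 (6.14%) against 47.2%, with adjusted p = 0.0001 for each. The shares of the 2 lists differed (odds ratio 9.34, Fisher's exact p = 1.76e-86), but the threshold of the Nup153 list is not stated, so this need not reflect the proteins. U2OS super-enhancers themselves touched a domain in 33 of 344 cases, 0.187 times the expectation. Super-enhancers with a Nup153 peak did so in 6 of 173 cases and those without in 27 of 171 (Fisher's exact p = 8.77e-05), and for Nup93 the numbers were 2 of 103 and 31 of 241 (p = 0.00103). The median distance to the nearest domain edge was 466.0 kb with and 570.9 kb without a Nup153 peak (permutation p = 0.384), and 785.3 kb with and 471.5 kb without a Nup93 peak (permutation p = 0.0102).

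Few Nup153 peaks were shared between the lines. Of the U2OS peaks 74 (4.06%) overlapped an IMR90 top peak, 4.04 times the expectation, and 376 (20.6%) a peak of the full list, 3.14 times. Of 344 U2OS super-enhancers 168 overlapped one of IMR90 cells. Among super-enhancers of a single line, U2OS Nup153 peaks marked 75 of 176 found only in U2OS and 95 of 442 found only in IMR90 cells (odds ratio 2.71, Fisher's exact p = 2.71e-07). IMR90 super-enhancers are longer (median 138.5 kb against 48.0 kb), and per Mb the U2OS peaks numbered 14.2 in the first set and 1.77 in the other. IMR90 top peaks marked 24 of 176 and 124 of 442 (odds ratio 0.405, Fisher's exact p = 0.000105), but per Mb they numbered 4.26 in super-enhancers found only in U2OS and 3.64 in those found only in IMR90 cells. The full IMR90 list marked 91 of 176 and 346 of 442, with 24.1 and 25.5 peaks per Mb.

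Genes nearest super-enhancers with a nucleoporin peak did not differ detectably in median response from genes nearest other super-enhancers. The medians were 0.02 and 0.12 for siNup153 in U2OS (162 and 146 genes, permutation p = 0.301), 0.02 and 0.08 for siNup93 (96 and 212 genes, p = 0.512), and -0.09 and -0.02 for siNup153 in IMR90 cells (171 and 394 genes, p = 0.193), where the median of all genes was 0.12. Without siNup153 replicate 1 the IMR90 difference of -0.11 passed the threshold (permutation p = 0.0465). Individual genes changed in both directions. A gene is placed at a super-enhancer here only because its start site was the nearest tested, whatever the distance. Among those named below, the start sites of CSF2, PLAU and MYC lay inside the super-enhancer. Those of EXT1, MRC2 and MN1 lay 132.1, 150.3 and 502.6 kb away. With siNup153 in U2OS cells the called genes at Nup153-marked super-enhancers numbered 65 rises and 54 falls, among them ARHGAP31 (super-enhancer on chromosome 3, 119012232 to 119043034; -2.03), the heparan sulfate synthesis gene EXT1 (1.95), KRT80 (1.52), CSF2 (1.46), SERTAD2 (1.39), CLIC4 (1.28), APBB2 (-1.25), MRC2 (-1.23), DLGAP1-AS1 (-1.42) and SEMA7A (-2.58). With siNup93 they numbered 40 rises and 38 falls, among them PLAU (urokinase, 2.00), MYC (1.83; super-enhancer on chromosome 8, 128746541 to 128773997, with 5 Nup93 peaks), SKAP1 (1.66), ST3GAL1 (1.62), S100A6 (1.36), SERTAD2 (1.32), MN1 (-1.54), DCBLD2 (-1.37) and LFNG (-1.34). MIR1204 (1.48 and 1.72), SNORA86 (-1.30) and LOC101927780 (1.67) are small or overlapping transcripts and uncertain.

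In IMR90 cells 48 genes at Nup153-marked super-enhancers rose and 62 fell. They included DHRS3 (2.53), the noncoding RNA gene FENDRR (2.49; super-enhancer on chromosome 16, 86372665 to 86553789, 2 peaks), EVA1A (-2.21), ARMC9 (1.74), PDGFB (1.54), MEX3A (1.51), SAMD14 (1.42), DPF3 (-1.41), IL6 (-1.39), GAS6 (-1.38), PALLD (1.32) and TBX2-AS1 (1.32). Fewer of the genes at marked super-enhancers were called than of genes at other super-enhancers (64.3% against 74.4%, Fisher's exact p = 0.0197). The share over all tested genes was 64.2%, so the genes at other super-enhancers stood out rather than those at marked ones. The difference was lost when any 1 of the 4 libraries was left out (-6.75 to -1.17 percentage points) and in other settings. As a set the 171 genes stood lower than other genes (camera adjusted p = 0.0175; adjusted p = 0.75 with an estimated correlation), and so did the 394 genes at super-enhancers without a peak (camera adjusted p = 0.0172; adjusted p = 0.75 with an estimated correlation). In U2OS cells the bound sets gave camera adjusted p = 0.776 for siNup153 and 0.9 for siNup93. The shares called were 73.5% against 71.9% (Fisher's exact p = 0.798) and 81.2% against 75.9% (p = 0.376). Over all tested genes the shares were lower, 60.1% for siNup153 and 68.0% for siNup93. Among super-enhancers of matched length the siNup93 difference between bound and other sets was 13.01 percentage points (Fisher's exact p = 0.0471).

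Super-enhancers went with the expression of their own line. In the control libraries 6735 of 13729 genes were higher in U2OS and 4664 higher in IMR90 cells. Genes nearest super-enhancers found only in U2OS were higher there (median log2 difference 0.89, 145 genes, 102 higher in U2OS against 23), and genes nearest those found only in IMR90 were lower in U2OS (-0.64, 412 genes, 109 against 266). The medians differed by 1.53 (permutation p = 1e-05, the smallest the resamples can give). Genes at super-enhancers of both lines lay between them (-0.16, 187 genes, 69 against 94). With all tested genes within 100 kb the difference was smaller, 0.85 (permutation p = 1e-05), and the median for super-enhancers of both lines was on the other side of 0 (0.11, 485 genes, 228 against 188), still between 0.51 and -0.34.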

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

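The differences between the lines below were tested by the interaction of the design; among the tests of explanations, that of a deeper knockdown was chosen after the result was seen. Genes responding differently to siNup153 numbered 5350 more positive and 3825 more negative in IMR90 than in U2OS cells, and 2912 genes were called in opposite directions and also passed the interaction test (1709 rising in IMR90 and falling in U2OS cells, 1203 the reverse). Response differences below are log2, IMR90 minus U2OS.

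Lists that differed by camera, with the median difference, were DNA replication (-1.62), mitosis (-1.36), YAP targets (-1.19), epithelial markers (-1.10), hypoxia and glycolysis (-0.78), lamina and envelope (-0.61), transport factors (-0.56), nucleoporins (-0.53, or -0.52 without NUP153), interferon response (0.89), cholesterol synthesis (0.75) and p53 targets (0.73). With an estimated correlation, 3 of these 11 held (adjusted p at most 0.0498), and the rest did not (0.0784 to 0.28).

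The targeted genes and the genes reported as leading the siNup153 rises and falls, 41 in all, each passed the interaction test. Apart from the targets, these genes were chosen for large changes in one of the lines, which favours a difference. The targets NUP153 and NUP93 differed by -1.06 and -0.69. Of the genes that led the U2OS rises, IL7R (-4.17), TMEM45A (-3.77), GPRC5A (-3.77), LINC01468 (-3.54), SNAPC1 (-3.32), SDPR (-2.75), COX7A2 (-2.54), COX7C (-2.43), LOC100505715 (-2.18) and PTN (-1.96) responded more negatively in IMR90 cells. Of those that led the U2OS falls, FAP (3.50), C8orf4 (3.39), TPRG1L (2.68), MGP (2.48), IGFBP7 (2.22), SEMA7A (2.06), LCP1 (1.99), LOC102467080 (1.98), HMGA2 (1.94) and TAGLN (0.96) responded more positively. Of the IMR90 rises, BMF differed by 4.61, RASGRP3 by 4.40, SLITRK6 by 4.36, MFAP2 by 3.84, VWA5A by 3.49, SOX4 by 3.40, SCG2 by 3.22, COLEC10 by 3.11, FAM105A by 2.69 and HTRA3 by 2.67. Of the IMR90 falls, IGFBP3 differed by -5.29, KRT7 by -3.22, KISS1 by -2.92, SERPINB2 by -2.91, CEMIP by -2.84, OXTR by -2.67, SSTR1 by -2.51, CLDN11 by -2.33 and CD274 by -2.28.

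The opposite course of the 2 lines was weighed against technical causes. Removing a trend on transcript length from both responses left r across genes at -0.205, and centring libraries on their medians left opposite calls at 1.41 times the number expected (2847 against 2019). A deeper knockdown in IMR90 cells of an otherwise equal response would give a positive r. The highest r over 20 settings, some of which cannot change r, was -0.176. This speaks only to a response that keeps its direction as the knockdown deepens. Without the replication and mitosis lists r was -0.202, but these hold 24 genes each of the 10991 compared. Leaving out so few could hardly move r, so a wider part of division genes in it stays open. A difference between the lines in biology may underlie the pattern. Culture medium, oxygen, timing and off-target effects of the siRNA that differ by line were not varied in the design and stay open. Depth of knockdown went with the line, with NUP153 at 40.4% of the control in U2OS and 16.4% in IMR90 cells. A response that changes direction with depth therefore stays open too.

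Peaks outside the chromosomes analysed were also present. Of the U2OS Nup153 peaks 22 lay on unplaced or random contigs and 2 on the mitochondrial genome, and of the Nup93 peaks 20 and 2.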

How the results depend on the processing

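Median-centred and quantile-scaled interactions, the settings of the counts at 2-fold, the split of the U2OS controls, the nucleoporin list without the targeted gene, and for super-enhancer genes median-centred libraries, super-enhancers of matched length and the full IMR90 list were added after the data were seen. Counts of genes called in each comparison stayed within 1.5 times of the reported ones in every alternative. Leaving out 1 library at a time gave 2997 to 4209 rises and 2703 to 4054 falls for siNup153 in U2OS, 3699 to 4948 and 3079 to 4458 for siNup93, 3825 to 4858 and 2007 to 3123 in IMR90 cells, and 4731 to 5400 more positive and 3409 to 3883 more negative genes in the interaction; an arm left with 1 library was assumed to vary like the others. The other alternatives gave 3127 to 4277 and 2786 to 4078, 3628 to 5472 and 2927 to 4604, 3489 to 5333 and 2299 to 3689, and 4587 to 6033 and 3755 to 4462. Of 204 named gene values in 3004 settings and genes together, 0 reversed and 14 lost the call, in the 5 gene and comparison pairs given in the report (RPS15, KRT7 and CLDN4 in U2OS, NUP93 and CLDN4 in IMR90). RPS15 also lost it without a filter (adjusted p = 0.0527) and after quantile scaling (0.0796), and KRT7 in the 4 libraries compared alone (0.0541). The pseudocount of 0.1 moved the covariance of the U2OS responses to 0.308, since low genes then spread more, with r at 0.578, and raised counts at 2-fold to those in the report and, for siNup153 in both lines, to 31 rises and 30 falls. With the controls split between the knockdowns, 1682 or 1646 genes rose and 1164 or 1162 fell in both, from fits of 3 libraries each. Among genes at FPKM 5 or more, 8 rose and 18 fell at least 2-fold in both lines.

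Among gene lists, the estimated correlation ended 41 of 44 camera calls and fry kept 44. The 3 calls kept were in the interaction, the fit with the most libraries. Loss of a call need not mean correlated genes. In IMR90 cells the estimate was -0.00587 for mitosis and -0.0272 for DNA replication, below the preset 0.01. The camera adjusted p of each still rose to 0.19. Fry put 30 uncalled lists past the threshold, since it compares them with no other genes. Its sign was opposite for 3 uncalled lists: ribosomal proteins in IMR90 cells (adjusted p = 0.357), and ER and amino-acid stress (0.189) and histone genes (0.861) in the interaction.

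Replicate numbers are shared across groups, but the labels do not say that they mark a batch. Deviations of same-numbered libraries correlated at 0.201 and 0.085 between the U2OS control and the siNup153 and siNup93 groups and at 0.06 in IMR90 cells, at 0.304 between siNup153 and siNup93 in U2OS, and at -0.552 between siNup153 in U2OS and IMR90 cells. With the replicate number as a block, 4277 genes rose and 4060 fell with siNup153 and 4874 and 4350 with siNup93 in U2OS, and 5119 and 2925 in IMR90 cells. A block cannot alter the fold changes of this balanced design, so r between the lines stayed at -0.21 and was not tested by it. With the block the IMR90 interferon list passed camera (camera adjusted p = 0.0408). The difference in share called at IMR90 super-enhancers was -5.11 percentage points with the block (Fisher's exact p = 0.219). The block changed no other list call.

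The 57 alternative overlap values kept their side of the expectation and of the threshold. The ratio at super-enhancers was 4.39 (Nup153) and 5.11 (Nup93) against peaks placed on random DNase sites in place of shifts. With at least 0.5 of a peak required inside, 0 peaks were counted and 0 expected at CTCF, DNase and H3K9me2 intervals, which are too narrow, so this was no test there. The higher-scoring part of the peaks was not run, since the lists give no score.

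Some differences in expression at super-enhancers, which were small, changed sign. With all genes within 100 kb the bound minus unbound median was 0.0394 for siNup153 in U2OS and 0.0049 in IMR90 cells, and the share called with siNup93 was -5.10 points, each opposite in sign to the reported value and short of the threshold. With a pseudocount of 0.1 the siNup153 share in U2OS was -1.82 points. Leaving out 1 library gave -0.86 to 6.75 points for that share (negative without siNup93 replicate 1 or 2), a median difference of -0.0823 to 0.019 for siNup93 (positive without siNup93 replicate 2), and in IMR90 cells a median difference of -0.1104 to -0.0049 (permutation p = 0.0465 without siNup153 replicate 1) and a share of -6.75 to -1.17 points. The IMR90 share was also short of the threshold with centred libraries (-1.07), matched lengths (-9.95, Fisher's exact p = 0.057) and the full peak list (-5.97, p = 0.234). The siNup93 share passed it with matched lengths (13.01, Fisher's exact p = 0.0471). The causes were not tested. With all tested genes within 100 kb the difference between genes of U2OS and IMR90 super-enhancers was 0.85. Simulated changes of 0.25 (log2) were recovered in 4% to 22% of cases where few genes changed; in the data, where at least 60.1% of genes were called, the smallest called changes were 0.116 to 0.141.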

Other observations

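Placement on DNase sites was chosen before the data were examined, but was read as a test of open chromatin only after the result was seen. The tests on super-enhancers of the own line, on the shared controls and on the control siRNA, and the comparisons of the first 2 paragraphs, were chosen after the results were seen. The genes named in the first paragraph were chosen after their values were seen. A smaller group of genes changed at least 2-fold in the same direction with siNup153 in both lines. The thyroid hormone deiodinase gene DIO2 rose by 1.96 in U2OS and 1.802 in IMR90 cells, the repair gene DDB2 by 1.61 and 1.36, CASP4 by 1.31 and 1.57, and BMP4 by 1.77 and 1.18. Falls were found for FN1 (-1.52 and -2.17), FGF5 (-1.30 and -2.38), the lysosomal lipase gene LIPA (-1.93 and -1.16) and PDCD1LG2, which encodes PD-L2 (-1.22 and -2.01). In all, 15 genes rose and 20, the target NUP153 among them, fell at least 2-fold in both lines (31 and 30 with a pseudocount of 0.1).

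Nup153 peaks inside and outside LBR domains differed. Of the 691 inside, 42.5% held a DNase site, 4.92% met H3K4me3, 1.01% a super-enhancer and 4.05% a Nup93 peak. Of the 1131 outside, 71.4%, 20.6%, 22.7% and 29.3% did (Fisher's exact p at most 1.31e-22). Super-enhancers and Nup93 peaks themselves touched LBR domains at 0.187 and 0.13 times the expectation. No baseline of other sites was compared, so the contrast need not be particular to Nup153 peaks. Nup93 peaks inside met a super-enhancer less often as well (3 of 61, 4.92%, against 164 of 932, 17.6%; Fisher's exact p = 0.00737), while their DNase share was 59.0% against 51.7% outside (Fisher's exact p = 0.292). Among genes with a U2OS Nup153 peak within 5 kb of the start site, 130 rose and 87 fell with siNup153, against 3804 and 3663 of the others (odds ratio 1.44, Fisher's exact p = 0.0107, adjusted p = 0.0321 over 3 such tests). The same count for Nup93 was 107 and 97 (Fisher's exact p = 0.832), and for IMR90 Nup153 423 and 218 (p = 0.323).

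The concentration of U2OS Nup153 and Nup93 peaks in super-enhancers was weighed against copy number and open chromatin. Gained regions would hold peaks and super-enhancers alike over long stretches. Moving each peak by 0.2 to 1 Mb left the observed number at 7.70 and 7.86 times the moved mean, so such stretches alone did not give it. The moved means, 34.3 and 21.2, still lay above the 14.98 and 9.36 of circular shifts. Part of the concentration was thus regional, and gained regions stay open as a cause of that part. Gains shorter than 0.2 Mb were not tested. Peaks placed on random DNase sites reached super-enhancers less often by 4.39 and 5.11 times, so the presence of DNase sites alone did not give the number. Sites were drawn with equal weight, since the lists give no score. More strongly open chromatin in super-enhancers therefore stays open as a cause. U2OS Nup153 peaks were 8.04 times denser in super-enhancers found only in U2OS than in those found only in IMR90 cells (95% exact interval 6.17 to 10.5). IMR90 top peaks were 0.855 times and those of the full list 1.058 times as dense in those of their own line, both within counting error of 1. These intervals treat peaks as independent and are too narrow, since peaks cluster (120 in 75 marked super-enhancers found only in U2OS). Nup153 contact may thus follow the super-enhancers of U2OS cells, but in IMR90 cells this cannot be told apart from no preference. The different thresholds of the lists, and the greater length of the IMR90 super-enhancers, stay open.

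The 224 genes that rose at least 2-fold with both knockdowns in U2OS cells (422 with a pseudocount of 0.1) were weighed against the shared controls, the control siRNA and transcript length. In 50 simulations with all 6 libraries drawn without change, controls included, 0 genes did so. Their spread was that of the fit, so the deposited controls themselves were not tested. With 1 control library for each knockdown, 222 or 229 genes rose by at least 1 on the log2 scale in both, by size alone. After a length trend was removed, 215 of the 224 (96.0%) stayed at least 2-fold higher in both. If the control siRNA lowered these genes in both lines and Nup153 loss left them unchanged in IMR90 cells, they would rise there too. Of 192 tested there 44 rose and 82 fell. Their median was -0.1464, against 0.12 for all genes and 0.00998 to 0.168 for 95% of 10000 random lists of matched level. The IMR90 values also hold that line's response to siNup153, which ran opposite to the U2OS response across genes (r = -0.21). The random lists were matched on level only, so these values cannot decide about the control siRNA. In the controls the 224 genes stood lower in U2OS than in IMR90 cells (median -0.74 against 0.207 for random lists matched on level in the knockdowns). Low U2OS controls would give this, but choosing genes that rose favours it. A shared response of U2OS cells to the loss of pore proteins may account for these genes. An effect of the control siRNA, in U2OS cells alone or in both lines, stays open, as does one of the 2 control libraries in U2OS cells.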
